A study of Homo sapiens with 3 samples.

How the data were processed

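The samples were 3 libraries from U2OS cells, which per the labels belong to the same batch: H3K27me3 ChIP from cells transfected with a control (Gl3), H3K27me3 ChIP from cells transfected with siORCA, and an input. Per the labels' protocols, cells were fixed in 1% formaldehyde for 10 min, chromatin was sonicated, and libraries were sequenced from a single end for 101 cycles. The submitters' processing notes name bcl2fastq, Trimmomatic, Bowtie2, SAMtools and T2T-CHM13, with no versions. The peak caller, its settings, the handling of duplicate and multiply aligned reads, and whether the input served as its background are not given in the sources used here. Peaks were deposited as 1 broadPeak list per ChIP library, and with 1 library per condition there were no replicates to pool or to test. The input was not analysed here. Many of the regions below lie in repeated sequence, where the treatment of multiply aligned reads sets how much signal a peak receives.

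Column 7 of each list holds the fold enrichment of the peak over its background as the authors' caller gave it, a ratio. The deposited −log10 p-value and −log10 q-value of each peak were taken as they stand. The lowest −log10 q was 1.00 in both lists, so each list stops at a q-value of about 0.1. The deposited score is 10 times the −log10 q cut to a whole number, in all but 10 control peaks and 8 siORCA peaks. These values were used to describe, rank or filter peaks within a list. No per-peak value was tested between lists.

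Coordinates are those of the files, printed from 1, on T2T-CHM13. Both lists held peaks on 22 autosomes and the X chromosome. The last peak end in either list stood for the end of each chromosome (3055 Mb in all). Peaks were not tied to genes, promoters or sequence content, because the gene table used here was on GRCh38 and coordinates were not converted. The planned counts of marked promoters, the gene lists, the shares of peaks in exons and introns, and the classes of gene density and GC content were therefore not analysed here, and regions were named in place of genes. The rule fixed before the data were examined named the 5 longest joined stretches of each list that held no base of the other list's peaks; the other regions, the fold classes, the peak-dense bins, the stretches, the strongest peaks and the solved depth were chosen after the data had been examined.

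Covered length is the merged length of the peaks. Overlap was counted in bases, or in peaks overlapped by at least 1 bp or over at least 50% of their length. Random expectation came from 100 placements of the siORCA peaks on their own chromosomes, and from 100 within their own 1 Mb bin. Broad domains joined peaks at most 3 kb apart and were at least 20 kb long. Peak-dense bins were 1 Mb bins with a mean coverage of both lists of at least 20%. Stretches covered in one list were runs of at least 5 consecutive 100 kb bins, covered over at least 5% in that list and under 2% in the other.

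No depth was given, so a relative depth was solved from the peaks. The model took the fold as (height + 1) / (background + 1) and the p-value as the Poisson probability of more than the whole part of the height, where the height is a whole number of reads times a step per read. The commonest pair of fold and −log10 p was held by 2398 control peaks (2.59 and 2.82) and 2294 siORCA peaks (3.00 and 3.20). Of 5 candidate heights in the control, the best came to 9.00 reads with a step of 0.926 and a background of 2.61 per base, and the next best missed a whole number by 0.19. Of 7 candidate heights in siORCA, the best came to 4.00 reads with a step of 1.00 and a background of 0.665 per base, and the next best missed by 0.051. Short peaks between this height and the next had to lie on a straight line of fold against −log10 p. Within 0.005, 1195 of 5765 control peaks and 3119 of 9257 siORCA peaks did so, against at most 129 and 244 for any other candidate. The best line was solved from the commonest pair and the slope to other common pairs, and short peaks with those pairs are counted. The other candidates were rounded to whole reads, which moves their lines off the commonest pair. The counts are therefore no independent support for the solved depth. Taking the commonest peak width, 100 bp in the control and 102 bp in siORCA, as the fragment length, the background per read gave a depth 4.32 times higher in the control. This value rests on the assumed form of the caller's model.

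The overlap and depth scripts were tested on simulated data. With a known part of the control peaks kept, 100% of peaks were classed correctly. On chromosome 21 the overlap of 0 peaks differed from a base-by-base count. Backgrounds and steps set in advance were recovered within 0.0022%. The peaks for this last test were drawn from the model that is solved. It therefore checks the solving and does not measure the accuracy of the solved depth. Alternatives fixed before the data were examined were a −log10 q of at least 2, a fold of at least 3, equal numbers of peaks, autosomes only, overlap by number of peaks, and gaps of 1 and 10 kb. Equal enrichment over background, the exclusion of peak-dense bins and placement within a 1 Mb bin were added later. Shares of peaks carry 95% Wilson intervals, which cover counting error only. Work was done with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.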

Results

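H3K27me3, the histone mark deposited by Polycomb repressive complex PRC2, was profiled by ChIP-seq in U2OS cells, a human osteosarcoma line. Cells had been transfected with a control (Gl3) or with siORCA, directed at ORCA, a protein that associates with the origin recognition complex. By its title, the series concerns the stabilization of Polycomb complexes by ORCA. Each condition had 1 ChIP library with a list of broad peaks, and an input library made up the 3 samples; no input values were analysed here. With 1 library per condition there was no replicate check, and no difference below was tested between conditions. The control list held 181157 peaks and the siORCA list 105729 peaks on 22 autosomes and the X chromosome of T2T-CHM13. The read depth was not given in the sources used here. Under an assumed Poisson model of the peak caller, the depth solved from the peaks' own folds and p-values was 4.32 times higher in the control library than in the siORCA library.

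Fewer and shorter peaks were called after siORCA. Peaks covered 206.8 Mb (6.77% of the chromosomes) in the control and 92.5 Mb (3.03%) in siORCA, a ratio of 0.447. The median peak width was 515 bp in the control and 414 bp in siORCA. Covered length was lower in siORCA on all 23 chromosomes. The lowest ratio of siORCA to control was 0.254 on chromosome 19, where 8.77 Mb was covered in the control and 2.23 Mb in siORCA. Chromosome 10 had a ratio of 0.277, chromosome 5 of 0.288 and chromosome 2 of 0.289. The highest ratios were 0.703 on chromosome 18, 0.696 on chromosome 1 and 0.676 on the X chromosome. On chromosome 1, the region from 122 to 143 Mb held 16.07 of 26.46 Mb in the control and 16.01 of 18.42 Mb in siORCA. On chromosome 18, the region from 15 to 21 Mb held 2.99 of 5.36 Mb and 3.27 of 3.77 Mb. Within each list, the median fold enrichment given by the authors was 2.73 in the control and 3.29 in siORCA. A fold limit of 3 in both lists turned the direction of the peak count, to 37608 control and 89244 siORCA peaks. It brought the ratio of covered length to 0.911. This limit lies above the median fold of the control list and below that of the siORCA list, so it removes more control peaks. Under the assumed depth model, however, the same fold stands for a lower enrichment over background in the control than in siORCA. Under the depth model, the commonest peak held 9 reads in the control and 4 reads in siORCA, 3.20 and 6.02 times the respective background, and this model has not been checked against reads.

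**Figure D1:**
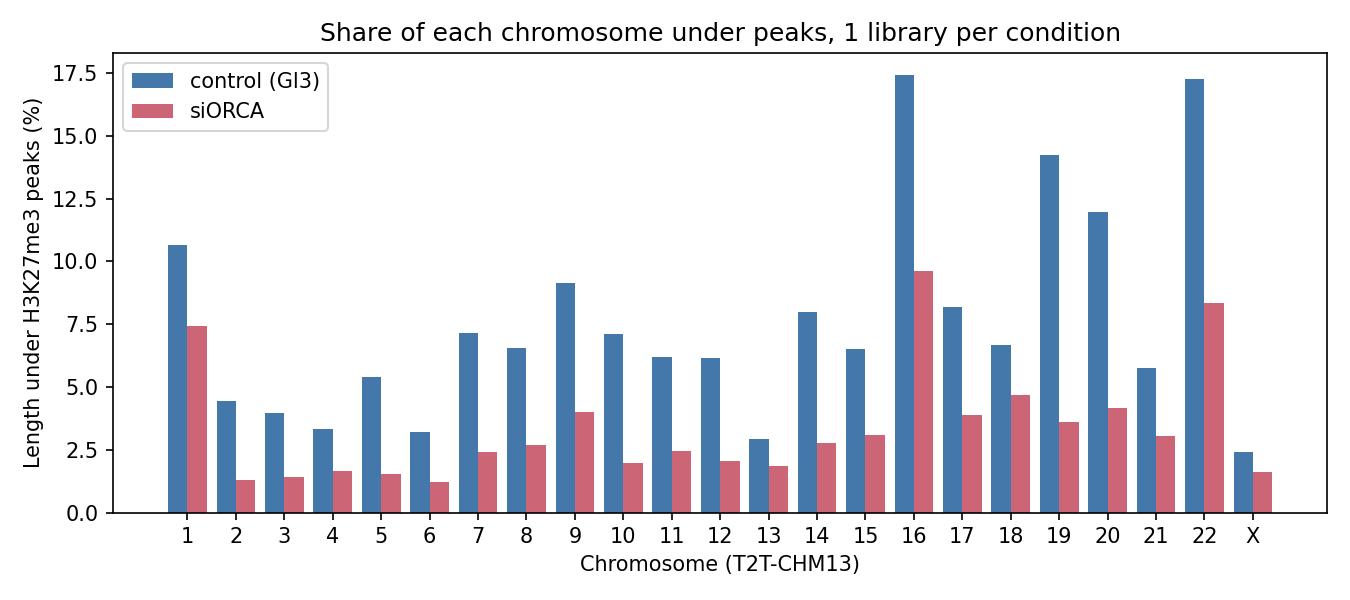
Share of each chromosome's length (%, y axis) under H3K27me3 peaks, by chromosome (x axis), with 1 bar for the control (Gl3) library and 1 for the siORCA library; there are no error bars because each condition has 1 library. The control bar is higher on all 23 chromosomes, from 2.42% on the X chromosome to 17.4% on chromosome 16.

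Of the siORCA peak length, 71.2% was also covered in the control, and of the control peak length, 31.9% was also covered in siORCA. With the siORCA peaks placed at random on their own chromosomes, these shares were 8.95% ± 0.48 (SD over 100 placements) and 3.92% ± 0.21. Placed at random within their own 1 Mb bin, they were 42.1% ± 0.25 and 16.1% ± 0.13. By number, 68.7% of siORCA peaks overlapped a control peak by at least 1 bp (95% Wilson interval 68.4 to 69.0%), and 33.7% of control peaks overlapped a siORCA peak (33.5 to 33.9%). With a fold of at least 3 in both lists, 46.8% of the siORCA length was also covered in the control, and 42.6% of the control length in siORCA. Without the peak-dense bins defined below, these shares were 53.0% and 12.5%. The intervals cover counting error only and treat peaks as independent.

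Sharing differed with the fold of the control peak. Of the length in control peaks with a fold of 4 and above (1581 peaks, 19.6 Mb), 93.2% was also covered in siORCA, against 21.7% for control peaks with a fold under 3 (143549 peaks, 111.9 Mb). By number, 72.7% and 28.7% of these peaks overlapped a siORCA peak. The order was not even along the scale: control peaks with a fold under 2.5 had 32.1% of their length shared, and those with a fold of 2.5 to 3 had 19.9%. The share was 94.0% from 4 to 5 and 88.8% at 5 and above. Peak-dense 1 Mb bins are defined below by a mean coverage of both lists of at least 20%. Outside them, the shares were 70.0% at a fold of 4 and above (680 peaks, 1.66 Mb) and 8.84% at a fold under 3. Most of the length at a fold of 4 and above thus lay in peak-dense bins. The fold was not separated from peak width or location.

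**Figure D2:**
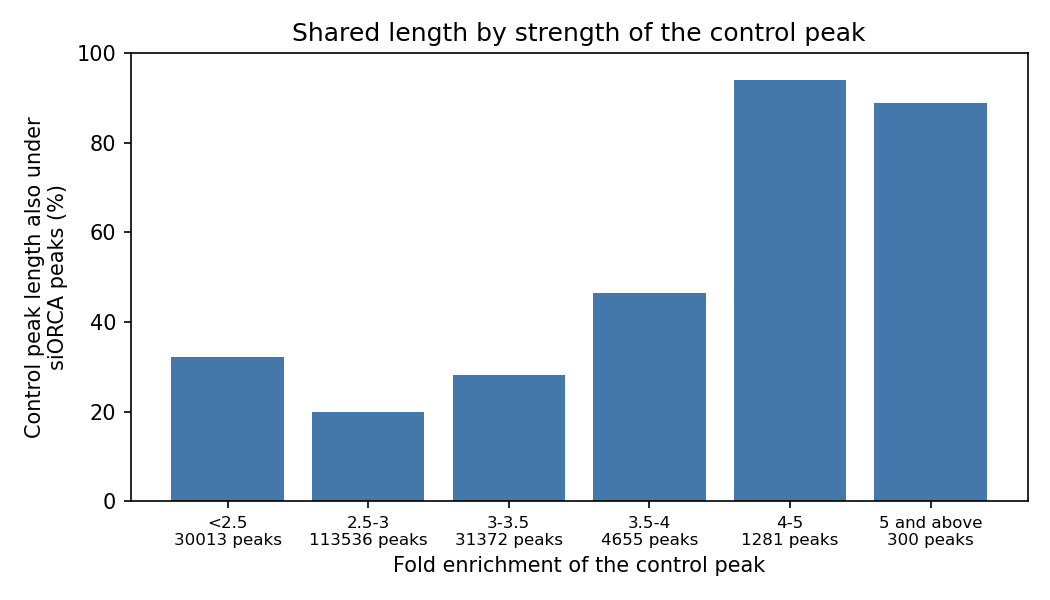
Share of control peak length also under siORCA peaks (%, y axis) in 6 classes of the control peak's fold enrichment (x axis), with the number of control peaks under each bar. The share is 94.0% in the class from 4 to 5 and 19.9% in the class from 2.5 to 3.

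The ratio of siORCA to control was higher in 1 Mb bins with dense peaks than in other bins. The 184 peak-dense bins made up 180.0 Mb and were covered over 91.5 Mb in the control and 65.4 Mb in siORCA, a ratio of 0.714. The other 2885 bins were covered over 115.2 Mb and 27.1 Mb, a ratio of 0.235. Peak-dense bins thus held 44.3% of the control peak length and 70.7% of the siORCA peak length. The definition of these bins was chosen after the lists had been examined and uses the coverage itself. The longest domain in both lists lay on chromosome 1, a chromosome that carries a large satellite block beside its centromere. It ran from 128992562 to 142250409 in the control, with 13.2 Mb of its 13.3 Mb under 97 peaks, and 13.1 Mb of it was also covered in siORCA. On chromosome 16, which carries another such block, the region from 39 to 53 Mb was covered over 9.78 Mb in the control and 7.07 Mb in siORCA. On chromosome 18 from 15 to 21 Mb, 2.99 Mb was covered in the control and 3.27 Mb in siORCA, and on chromosome 6 from 58 to 61 Mb the values were 0.747 Mb and 0.910 Mb. Of 37 blocks of adjacent peak-dense bins, 5 were covered over at least as much length in siORCA as in the control.

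Of the 37 blocks, 4 had a ratio below the 0.2355 of the bins that were not peak-dense. They are the lowest of the 37 and were picked for that. Chromosome 20 from 43 to 45 Mb was covered over 0.963 Mb in the control and 0.0448 Mb in siORCA (2.24%). Chromosome 19 from 59 Mb to its end was covered over 1.16 Mb and 0.123 Mb, and from 54 to 56 Mb over 0.842 Mb and 0.130 Mb. Chromosome 17 from 34 to 36 Mb was covered over 0.835 Mb and 0.115 Mb. Among single 1 Mb bins, the largest differences were on chromosome 7 from 64 to 65 Mb, with 0.808 Mb in the control and 0.106 Mb in siORCA, and on chromosome 20 from 32 to 33 Mb, with 0.8996 Mb and 0.241 Mb. In all, 245 bins, 101 of them peak-dense, were lower in siORCA by at least 0.1 Mb, and 22 were higher by as much. The 22 higher bins comprised 15 peak-dense bins and 7 bins in the initial 10 Mb of acrocentric chromosomes. The first and last 1 Mb of each chromosome, which border the telomeres, were covered over 13.99% in the control and 6.49% in siORCA, a ratio of 0.464, close to that of whole chromosomes.

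Broad domains, made by joining peaks at most 3 kb apart and keeping those of at least 20 kb, numbered 1708 in the control (156.4 Mb) and 823 in siORCA (103.7 Mb). Without any base of the other list's peaks were 86 of the control domains and 11 of the siORCA domains; the other domains share at least 1 base, which does not measure how much of a domain was shared. A fold limit of 3 turned the direction, with 730 domains (54.8 Mb) in the control and 941 (94.9 Mb) in siORCA. That limit lies above the commonest fold of the control list (2.59) and at that of the siORCA list (3.00). It therefore removes more control peaks, although under the assumed depth model it asks for a lower enrichment over background in the control. The 5 longest control stretches with no siORCA peak were on the X chromosome from 57653427 to 57763103 (109.7 kb, 49 peaks), on chromosome 4 from 239392 to 327819 (88.4 kb, 42 peaks), on chromosome 15 from 13909401 to 13973710 (64.3 kb, 34 peaks) and from 14130462 to 14190030 (59.6 kb, 30 peaks), and on chromosome 19 from 39530572 to 39581465 (50.9 kb, 18 peaks). Their highest peak folds lay between 3.43 and 3.59. The 5 longest siORCA stretches with no control peak were shorter. They lay on chromosome 17 from 23037367 to 23069146 (31.8 kb, 17 peaks) and from 23072487 to 23094877 (22.4 kb, 12 peaks), on chromosome 14 from 2473584 to 2498465 (24.9 kb, 12 peaks), on chromosome 1 from 144418399 to 144443005 (24.6 kb, 14 peaks), and on chromosome 21 from 4912329 to 4934571 (22.2 kb, 10 peaks).

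Long stretches covered in siORCA and nearly empty in the control lay on the short arms of the acrocentric chromosomes 13, 14, 15, 21 and 22, the arms that carry the ribosomal DNA arrays. Among stretches of at least 5 consecutive 100 kb bins, each covered over at least 5% in one list and under 2% in the other, 5 were covered in siORCA, and each was on a different acrocentric chromosome. They spanned 5.8 to 9.4 Mb on chromosome 13, 2.1 to 2.8 Mb on chromosome 14, 2.5 to 4.7 Mb on chromosome 15, 3.1 to 5.6 Mb on chromosome 21 and 4.8 to 5.7 Mb on chromosome 22, 9.9 Mb in all. They held 2166 siORCA peaks and 58 control peaks. Over the whole initial 10 Mb of the 5 chromosomes, coverage was lower in siORCA, 5.31 Mb against 8.30 Mb in the control, with a ratio of 0.375 on chromosome 14, 0.583 on chromosome 22, 0.999 on chromosome 15, 1.01 on chromosome 21 and 1.47 on chromosome 13. The siORCA peaks covered 9.40% of the stretch on chromosome 13, 18.7% on chromosome 14, 14.8% on chromosome 15, 17.7% on chromosome 21 and 17.6% on chromosome 22, and control peaks covered from 0.0353% to 0.758%. The siORCA peaks there had median folds from 3.21 to 3.29, against 3.29 in the whole list. Their median widths ran from 392 to 523 bp, against 414 bp. Their median −log10 q ran from 1.55 to 1.66, below the 1.73 of the whole list. In the opposite direction, 78 stretches on 19 chromosomes, 48.2 Mb in all, were covered in the control and under 2% in each siORCA bin. They held 7577 control peaks and 888 siORCA peaks. Bins outside the peak-dense class were thinly covered in siORCA as a whole, over 27.1 Mb of 2874.8 Mb. Low siORCA coverage was therefore not particular to the 78 stretches. The longest of the 78 were 1.1 Mb, among them chromosome 16 from 25.9 to 27 Mb, with 35.2% covered in the control and 0.769% in siORCA. These stretches were defined after the lists had been examined.

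**Figure D3:**
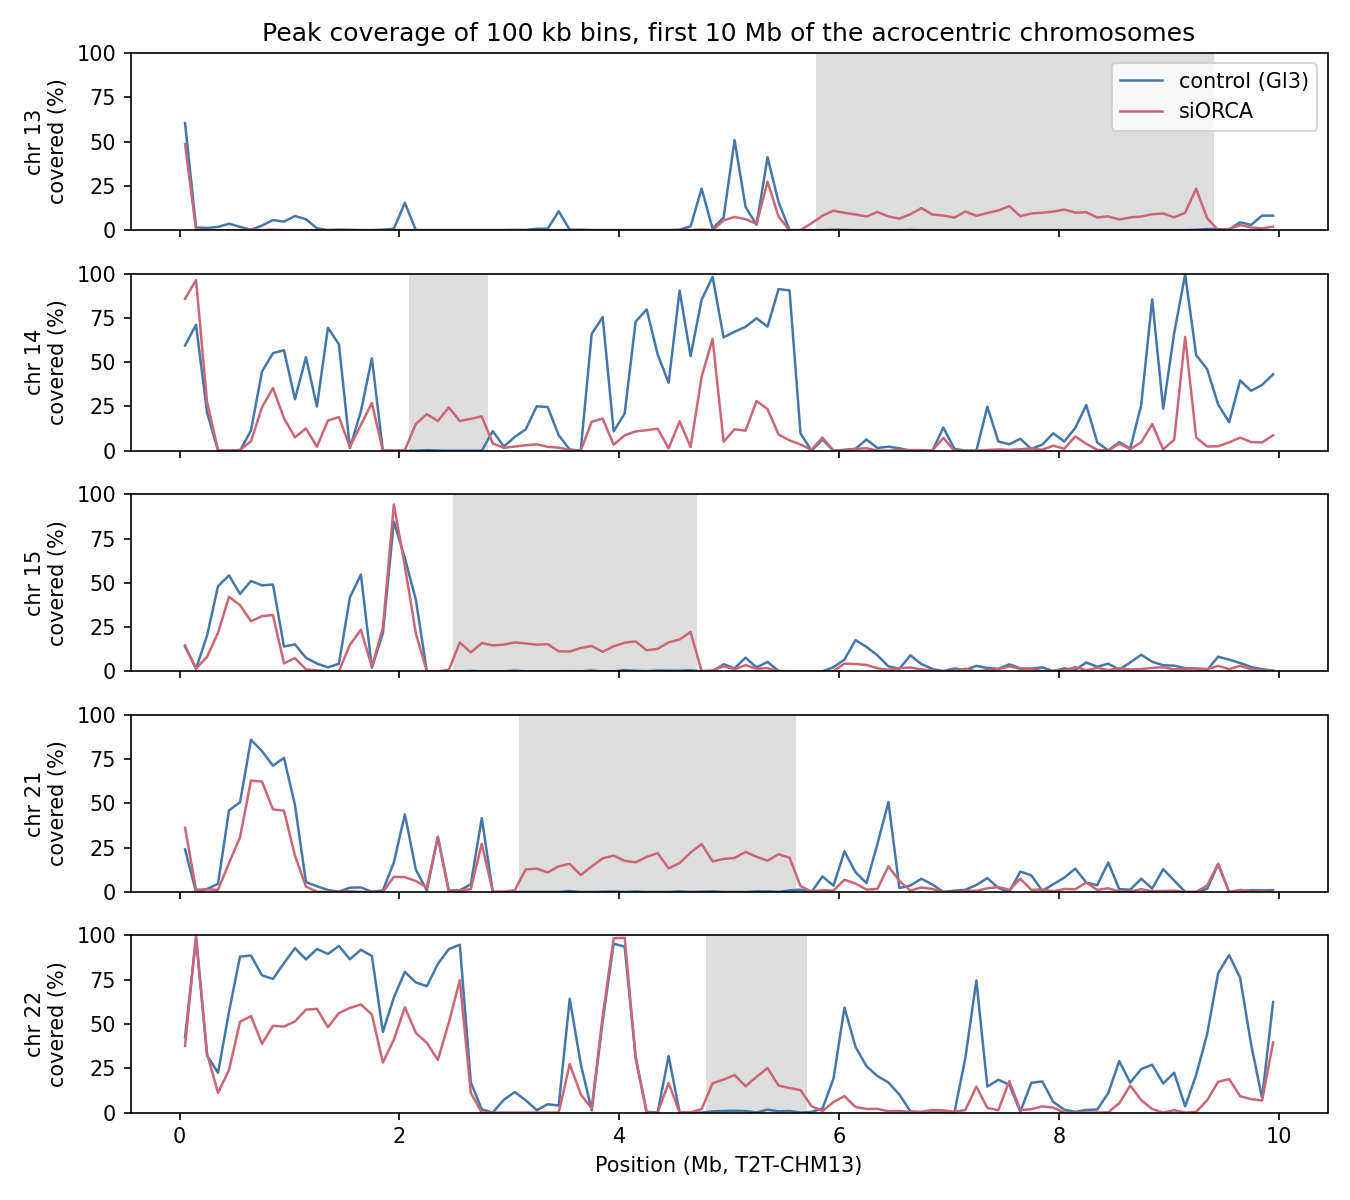
Share of each 100 kb bin under peaks (%, y axis) along the initial 10 Mb (x axis, Mb) of chromosomes 13, 14, 15, 21 and 22, for the control (Gl3) and siORCA libraries, with the 5 stretches covered in siORCA alone shaded in grey. In the shaded stretches the siORCA line is at 5% or above and the control line under 2% in each bin.

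The strongest peaks of at least 1 kb were regions marked in both lists. In the siORCA list they were on chromosome 3 from 37709282 to 37714456, with a fold of 20.9, on chromosome 8 from 144816549 to 144828478, with 19.01, and on chromosome 8 from 86081473 to 86946576, an 865.1 kb peak with 17.8. In the control list they were on chromosome 2 from 94831032 to 94865166, with a fold of 10.1, on chromosome 2 from 89837143 to 89866850, with 9.87, and on chromosome 9 from 44898838 to 44942341, with 9.66. Peaks of the other list covered from 88.0% to 100% of each of them. The 865.1 kb region on chromosome 8 was called as 12 peaks in the control, with a length-weighted mean fold of 4.71. Folds are the authors' own values within each list and were not tested between lists.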

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

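With 1 library per condition, no library could be left out, and no paired analysis was possible because no condition had a second library. The alternatives on promoters and gene lists were not run, since peaks were not tied to genes. With a −log10 q of at least 2, and on autosomes only, siORCA stayed lower in peaks, covered length, domains and domain length. With equal numbers of peaks, taken by −log10 p, it stayed lower in covered length, domains and domain length. The number of peaks was then fixed and was not compared. Domain length came near parity there, with a ratio of 0.910 against 0.663 in the main setting. With gaps of 1 and 10 kb the number and length of domains stayed lower in siORCA. Each of these ratios was within 1.5 times the main ratio. None of these settings brings the lists to equal depth. At a given enrichment, −log10 p and −log10 q grow with depth, so limits on them favour the control if it is deeper. The kept direction therefore cannot decide between depth and a loss of the mark. A fold of at least 3 changed the ratios of siORCA to control to 2.37 for peaks, 0.911 for covered length, 1.29 for domains and 1.73 for domain length. This limit lies above the median fold of the control list (2.73) and below that of the siORCA list (3.29), so it removes more control peaks. Under the assumed depth model it is nevertheless a lower limit on enrichment over background in the control than in siORCA. Equal enrichment over background (chosen after seeing the data; 6.02 times background, a control fold of 4.63) kept 508 control peaks and 88807 siORCA peaks. Its ratios were 175 for peaks, 16.1 for covered length, 18.7 for domains and 19.1 for domain length. That limit was taken from the commonest siORCA peak, so it keeps most of that list by construction. Without peak-dense bins (also chosen after seeing the data) the ratio of peaks was 0.418, and the ratios were 0.236 for covered length, 0.241 for domains and 0.213 for domain length. The share of control length also covered in siORCA was 29.1% with a −log10 q of at least 2, 42.6% with a fold of at least 3 and 36.2% with equal numbers. It was 12.5% without peak-dense bins, 33.7% as peaks overlapped by 1 bp and 19.8% as peaks overlapped over 50% of their length. For the 508 control peaks at equal enrichment it was 91.7%, but there the limit was set on the control list only, so this share is not comparable with the others. The share of siORCA length also covered in the control was 73.3%, 46.8% and 66.4% under the same limits on q, fold and number, 71.5% on autosomes, 53.0% without peak-dense bins, 68.7% as peaks overlapped by 1 bp and 54.9% over 50% of their length. For these shares the cause was not tested. No depth was measured; if the siORCA library is shallower, as the assumed model has it, a region empty in its list was not shown to lack the mark.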

Other observations

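Apart from the fold limit of 3 applied to both lists, the tests in this part were chosen after the lists had been seen.

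The stretches covered in siORCA alone carried a regular spacing. The autocorrelation of their siORCA peaks, searched at lags of 30 to 60 kb, was highest at 47.0 kb on chromosome 13, 44.1 kb on chromosome 14, 43.7 kb on chromosome 15, 44.4 kb on chromosome 21 and 43.4 kb on chromosome 22. Its height ranged from 0.272 to 0.418, and the highest value over 1000 random placements per stretch was 0.135. Under 5 other limits on coverage and length, the scan found 4 or 5 stretches each time, on 4 or 5 of the acrocentric chromosomes and 0 elsewhere. On other chromosomes, the bins where siORCA coverage exceeded control coverage most were on chromosome 1 from 122 to 126 Mb (0.158 to 0.238 Mb per bin in the control and 0.346 to 0.431 Mb in siORCA), on chromosome 11 from 52 to 53 Mb (0.428 and 0.596 Mb) and on chromosome 20 from 28 to 29 Mb (0.414 and 0.580 Mb).

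The smaller covered length in siORCA has a technical explanation to weigh, the difference in depth. Under an assumed model of the peak caller, the solved depth was 4.32 times higher in the control library. The model was met by 1195 of 5765 short control peaks and 3119 of 9257 short siORCA peaks. These counts include peaks from which the model was solved, so they are no independent support for it. Weak control peaks were shared far less than strong ones: 93.2% of control length at a fold of 4 and above was shared, against 21.7% at a fold under 3 (72.7% and 28.7% by number, and 70.0% and 8.84% of length outside peak-dense bins). This order is not a clear mark of depth, since a proportional loss of the mark would also spare strong peaks. A rise of the share through all fold classes, set out for lower depth after the data were seen, was not met. The share was 32.1% at a fold under 2.5 and 19.9% from 2.5 to 3. It was 94.0% from 4 to 5 and 88.8% at 5 and above, while by number it rose there from 70.6% to 82.0%. The first fall cannot decide on depth. Folds under 2.5 lie below that of the commonest control peak (2.59), so the fold need not rank these peaks by reads. A loss of H3K27me3 after ORCA depletion may contribute and cannot be told apart from depth here. Only peak lists were used, so the libraries could not be brought to equal depth, and each condition has 1 library. With a fold of at least 3 in both lists the ratio of covered length was 0.911. Under the assumed model, however, the same fold stands for a lower enrichment over background in the control than in siORCA.

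The siORCA-only stretches on the acrocentric chromosomes run opposite to the lower covered length of the siORCA list as a whole. The spacing argues against calls placed at random within a stretch, since 0 of 1000 random placements in any stretch gave as high an autocorrelation. It cannot decide on chance calls at low depth, because background reads over repeated sequence could carry the same spacing. A candidate explanation for the spacing is a tandem array such as ribosomal DNA, whose unit is of about this length; the lowest autocorrelation of 0.272 and the restriction to acrocentric short arms fit it, while no sequence was matched. Whether siORCA cells gained H3K27me3 over these stretches (14.1% covered) or the siORCA library held more reads from them for technical reasons, such as amplification or alignment of repeated sequence, cannot be told apart, since the peaks do not stand out in fold (lowest median 3.21) and no second library or input was analysed. A gain, if real, would be open to a direct test by ChIP-qPCR over the ribosomal DNA unit in replicate knockdowns.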
